A study of Mus musculus with 6 samples.

How the data were processed

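Fetal liver hematopoietic stem and progenitor cells of C57BL/6 mice at embryonic day 15.5 were profiled by droplet single-cell RNA sequencing. Per the labels' protocols, cells were sorted, frozen, thawed and loaded on a 10x Chromium V3 chip. The samples fall into 2 groups of 3, saline and pIC, taken from the sample titles. The pIC group is named Poly1C in the cell number table. Poly(I:C) is a synthetic double-stranded RNA that mimics viral RNA, and the series title names maternal immune activation. The labels describe each sample as a flkswitch by wild-type fetus. In such mice recombination driven by the Flt3 locus switches a cell from a red to a green fluorescent reporter.

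The submitters' processing notes name STARsolo (an aligner and counter for single-cell reads), Seurat (single-cell clustering) and deepTools, with the mm10 genome build; they give no versions. Filters on cells, treatment of doublets, normalization, correction between samples and clustering settings are not given in the sources used here. 2 deposited tables were analysed. The first gives, for each of 14 clusters, the count of cells in all samples, in saline and in pIC, as the authors deposited it. The same table holds the authors' percent of cells per cluster and p-values of a Fisher test per cluster. Its adjusted p-value is the p-value multiplied by the number of clusters, from the values. No column gives a count per sample, so neither a mean with SD nor any test over samples could be made, and the authors' pooled values are printed without n.

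The second deposited table lists marker genes of each cluster against all other cells, over both groups together, in the layout of Seurat's marker function. It therefore holds no comparison of pIC with saline within a cluster. The authors deposited a log fold change for each gene, taken here as a natural log (ln) because the column name is that of Seurat releases that used it; the file does not state the base. Its lowest value is 0.15. Values are printed on that scale and not turned into folds. The table has positive markers only. The deposited detection fraction is the share of cells with the gene detected, inside and outside the cluster, and is printed as a percent. The deposited marker p-value was computed over cells; its adjusted form is the p-value times 38046 genes. The 5537 listed pairs of gene and cluster cover 3017 genes. Of these pairs, 5519 had an adjusted p-value under 0.05 and were used as markers.

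The 2 tables were checked against each other. Overall detection, computed from cluster sizes and the deposited shares, differed by at most 0.000958 between clusters for the 1419 genes listed in 2 or more clusters, within the rounding step of 0.001. The deposited percents were recomputed to within 0.00498 points.

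Shares of cells were given exact Clopper-Pearson 95% intervals. The ratio of the pIC to the saline share was given an exact 95% interval conditional on the cells of the cluster. Intervals cover counting error only, not differences between fetuses, litters or libraries. In binomial draws with known ratios the interval covered the true ratio in 94.6% to 97.5% of runs. The depth per cell and per sample is not known from these tables; the depth behind each share is the 11528 saline and 11977 pIC cells.

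Before the data were examined, 20 gene lists were fixed, 13 of cell type markers and 7 of responses, along with the rule for named genes. The rule takes the 5 markers with the largest fold per cluster, and up to 4 members with the largest fold of each list over-represented in a cluster. Genes outside it are said to be chosen after their values were seen. 1 gene that the rule takes is not reported here. A list was compared with a cluster's markers by Fisher's exact test, two-sided, among the 3017 genes of the table, with Benjamini-Hochberg adjustment over 266 pairs of list and cluster. Genes are not independent replicates, and clusters were formed from the expression of such genes, so these tests describe the clusters and are not findings about treatment. Tested on simulated data, the list test called 99.3% of 140 planted lists of 20 genes, 10 of them from the cluster, and 0.0% of pairs with random lists. All 20 planted genes were in the table. Most of the lists used had fewer genes there, such as 2 for hepatocytes, and random lists are not sets of genes expressed together. These rates therefore need not hold for the lists used.

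A cluster was called after a cell type where that list had the most members among its 10 largest folds, with at least 2 there and 3 among all markers; ties went to the list with the larger share of its members. This scoring was set after the table was seen. Other clusters stayed unnamed. Names rebuilt in this way may differ from the study's. Planned tests over samples (edgeR's quasi-likelihood test of cell counts among them) were replaced by pooled values, since the file holds group totals only. Clusters were therefore ordered by the size of the ratio in place of a test. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names; 2937 of the 3017 symbols have an entry in the gene name table, and the annotation the authors used is not given in the sources used here. Analyses used Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3.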

Results

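The data collected were the numbers of fetal liver stem and progenitor cells in 14 expression clusters, pooled over the samples of each treatment, and the marker genes of those clusters. The table held 23505 cells, 11528 from saline and 11977 from pIC fetuses. The series title names the question as how maternal immune activation affects fetal hematopoietic development. The comparison that the deposited values allow is the share of cells in each cluster in pooled pIC against pooled saline cells. Cells are not replicates, and no test between treatments was made.

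In pooled pIC cells, the stem cell-like cluster and the 4 unnamed clusters together made up smaller shares. Most clusters with lymphoid, granulocyte or monocyte and dendritic markers made up larger shares. The HSC-like cluster 2 held 13.9% of saline cells (1601 cells, 95% interval 13.3% to 14.5%) and 8.17% of pIC cells (979 cells, 7.69% to 8.68%). The ratio of the pIC to the saline share was 0.589 (0.543 to 0.638). The lower share was not particular to this cluster. The 4 unnamed clusters together held 42.7% of saline and 35.3% of pIC cells, a ratio of 0.826 (0.793 to 0.861). Of these, clusters 4 and 7 had the HSC list over-represented. Cluster 8, where that list was not over-represented, had a ratio of 0.625 (0.563 to 0.695), an interval that overlaps that of cluster 2. The 3 clusters with lymphoid names together held 10.9% of saline and 14.9% of pIC cells, a ratio of 1.36 (1.27 to 1.46). The 2 granulocyte-like clusters held 16.3% and 21.9%, a ratio of 1.34 (1.26 to 1.42), though the granulocyte list was over-represented in neither. The 3 monocyte and dendritic-like clusters held 15.0% and 18.8%, a ratio of 1.25 (1.18 to 1.33). The megakaryocyte-like cluster 13 held 1.15% and 0.985%, a ratio of 0.860 (0.665 to 1.11), with a counting interval that includes 1. The sort that selected the cells can set all of these shares, and whether each of the 3 samples of a group shows the group's value is not known. Nor is it known whether the genes that define a cluster differed between treatments, which would move cells between clusters.

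**Figure D1:**
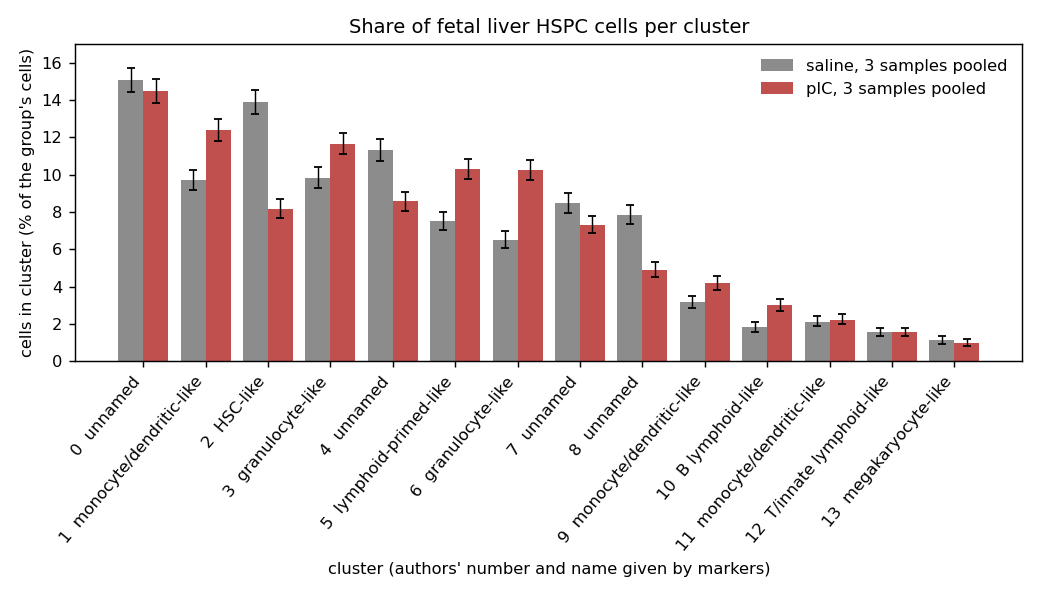
Percent of each treatment's cells in the 14 clusters; bars are the pooled saline (grey) and pooled pIC (red) cells and error bars are exact 95% intervals for counting error. The HSC-like cluster 2 stands at 13.9% in saline and 8.17% in pIC, while granulocyte-like cluster 6 stands at 6.50% and 10.2%.

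The markers of cluster 2 held most of the listed genes of hematopoietic stem cells. They included 16 of the 17 HSC list genes in the table (Fisher's exact test, adjusted p = 1.9e-09), 3 of them among its 10 largest folds, where 2 erythroid list genes stood as well. The largest folds in the authors' deposited table were those of the beta-globin gene Hbb-bt (1.03) and of Ltb (0.98), which encodes lymphotoxin beta and was detected in 90.9% of cells inside against 49.4% outside. In the authors' deposited table Hlf, a transcription factor of stem cells, had a log fold change of 0.90 and was detected in 95.4% of cells inside against 53.6% outside. Mecom, a regulator of stem cell maintenance, had a log fold change of 0.78 in the authors' deposited table and was detected in 76.9% against 28.2%. Mllt3 (0.69) and Mycn (0.69) followed in the authors' deposited table. Hlf lies on chromosome 11 from 90336536 to 90390895, Mecom on chromosome 3 from 29951296 to 30548008 and Mllt3 on chromosome 4 from 87769925 to 88033364 (GRCm38), all on the minus strand. The fetal program list was over-represented as well, with 8 of 9 genes (Fisher's exact test, adjusted p = 0.00021), among them the imprinted transcripts Meg3 and H19. None of the 41 S phase and none of the 50 G2 and M phase genes was a marker (Fisher's exact test, adjusted p = 0.0021 and 0.00042, the first 0.35 at a log fold change minimum of 0.25).

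The same cluster carried signs that can go with low RNA content or quality. It listed 9 mitochondrially encoded genes, against at most 3 in any other cluster. The mitochondrial ribosomal RNA mt-Rnr2, chosen after its value was seen, had a log fold change of 0.70 in the authors' deposited table. For 213 of its 592 listed genes, detection was lower inside the cluster than outside despite the positive fold. In the other 13 clusters together this held for 24 of 4945 listed pairs. Hbb-bt was detected in 85.9% of the cells of the HSC-like cluster. It was detected in 91.5% of cells in cluster 7, 86.9% in cluster 4 and 77.8% in cluster 0. Clusters 0, 4 and 7 each listed 0 mitochondrially encoded genes. They listed 0, 1 and 0 genes with lower detection inside. Frequent Hbb-bt detection was thus not particular to the cluster with these signs. Hbb-bt was also detected in 44.5% of the cells of the 10 clusters that do not list it.

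The HSC list was also over-represented in clusters 4 and 7, which were rich in cell cycle genes and stayed unnamed. Cluster 4 held 8 of the 17 HSC genes (Fisher's exact test, adjusted p = 0.0049) and 47 of 50 G2 and M phase genes (1.0e-37), led in the authors' deposited table by Ube2c (1.10), Cenpa (0.99) and Cenpf (0.99), which act in mitosis. Cluster 7 held 9 of the 17 HSC genes (adjusted p = 0.00019) and all 41 S phase genes (7.7e-40). Its largest fold in the authors' deposited table was that of Hbb-bt (1.00), followed by the histone gene Hist1h2ap (0.84). The S phase genes included Tyms (0.68), an enzyme of thymidylate synthesis, and Pcna (0.42), the sliding clamp of replication, in the authors' deposited table. Cluster 7 also held 5 of 9 fetal program genes (adjusted p = 0.0083, and 1 at a log fold change minimum of 0.25). The HSC list calls of both clusters ended at a log fold change minimum of 0.25 (adjusted p = 1 and 0.15). Cluster 4 held 11.3% of saline and 8.57% of pIC cells, a ratio of 0.758 (0.698 to 0.823). Cluster 7 held 8.48% and 7.32%, a ratio of 0.864 (0.788 to 0.947). Clusters 2, 4 and 7 together held 33.7% of saline and 24.1% of pIC cells, a ratio of 0.715 (0.681 to 0.750).

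Clusters 0 and 8 were unnamed, and the HSC list was over-represented in neither. Cluster 0, the largest, was led in the authors' deposited table by Ung (0.59), a DNA repair enzyme, and Ctla2a (0.55), and held 14 of 41 S phase genes (Fisher's exact test, adjusted p = 6.2e-09). It held 15.1% of saline and 14.5% of pIC cells, a ratio of 0.961 (0.898 to 1.03). Cluster 8 had the fewest markers, 73, led in the authors' deposited table by the histone gene Hist1h2bc (1.21) and the cyclin Ccnb2 (0.51). It held 7.85% of saline and 4.91% of pIC cells, a ratio of 0.625 (0.563 to 0.695).

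The granulocyte-like clusters 3 and 6 shared Mpo, which encodes myeloperoxidase, and Ctsg, a neutrophil protease, among their 10 largest folds. Mpo lies on chromosome 11 from 87793581 to 87804413 on the plus strand and Ctsg on chromosome 14 from 56099881 to 56102574 on the minus strand. In the authors' deposited table Mpo had a log fold change of 0.70 in cluster 3 and 0.85 in cluster 6, with detection of 96.4% and 96.8% inside against 63.6% and 64.4% outside. The granulocyte list held 9 genes of the table, of which 3 were markers of cluster 3 and 4 of cluster 6, and it was not over-represented in either (adjusted p = 0.22 and 0.17). Cluster 3 held 32 of 50 G2 and M phase genes (Fisher's exact test, adjusted p = 5.7e-20), and its largest fold was that of Ube2c (0.88 in the authors' deposited table). Cluster 6 held 14 of 41 S phase genes (adjusted p = 0.024, and 0.44 at a log fold change minimum of 0.25) and 1 of 50 G2 and M phase genes (adjusted p = 0.035, and 0.29 at that minimum). Cluster 6 held 6.50% of saline and 10.2% of pIC cells, a ratio of 1.58 (1.44 to 1.73). Cluster 3 held 9.84% and 11.7%, a ratio of 1.18 (1.09 to 1.28).

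**Figure D2:**
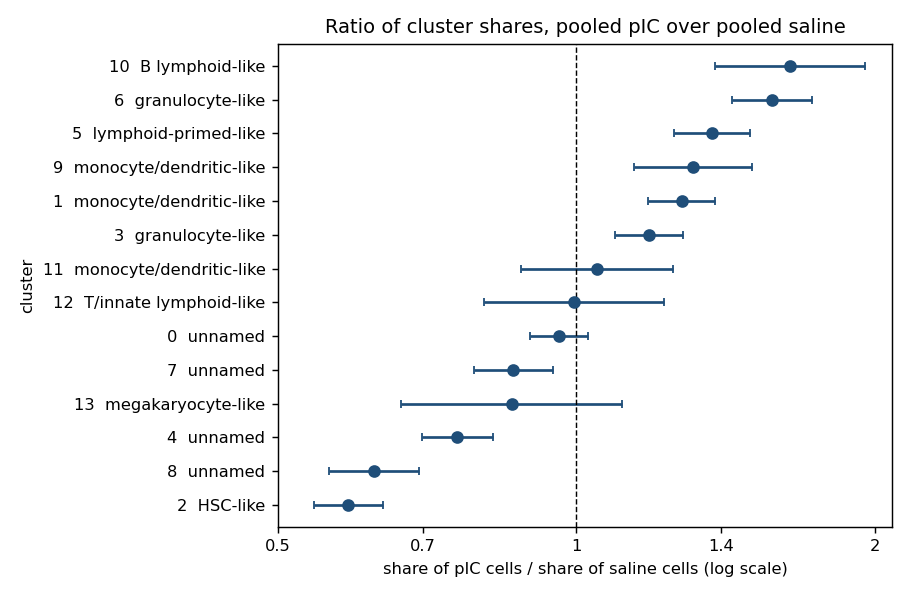
Ratio of the share of pooled pIC cells to the share of pooled saline cells for each cluster on a log axis; points are ratios, bars exact 95% intervals for counting error, and the dashed line marks a ratio of 1. The ratios run from 0.589 in the HSC-like cluster 2 to 1.64 in the B lymphoid-like cluster 10.

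The 3 clusters with lymphoid names differed in their ratios. The B lymphoid-like cluster 10 had the highest ratio of the 14 clusters, 1.64 (1.38 to 1.96), with 1.83% of saline (211 cells) and 3.01% of pIC cells (360 cells). It held 13 of 14 B lymphoid genes (Fisher's exact test, adjusted p = 2.5e-09). In the authors' deposited table it was led by Ebf1 (2.15), a transcription factor of B lineage commitment, by Vpreb3 (1.99) and by the receptor component Cd79a (1.98). Ebf1 lies on chromosome 11 from 44617317 to 45008091 on the plus strand. Cluster 10 also held 11 of 17 lymphoid-primed genes (adjusted p = 3.4e-05) and 37 of 50 G2 and M phase genes (2.7e-20). The lymphoid-primed list shares 4 genes with other lists. Among them are Ighm and Rag1 with the B lymphoid list and Tcf7 with the T and innate lymphoid list. The calls of these lists are therefore not independent of each other. The lymphoid-primed cluster 5 held 7.52% and 10.3%, a ratio of 1.37 (1.25 to 1.50). Its largest folds in the authors' deposited table were those of the T cell receptor constant gene Trbc2 (1.22), Mzb1 (1.12), Tmem108 (0.93), Ebf1 (0.75) and Cox6a2 (0.75). Trbc2 was detected in 81.4% of its cells against 26.5% outside. Cluster 5 held 11 of 17 genes of the multipotent and lymphoid-primed list (adjusted p = 1.7e-09), among them Ighm (0.72), Il7r (0.64), Il12a (0.58) and Notch1 (0.52) in the authors' deposited table. Il7r, the interleukin-7 receptor gene on chromosome 15 from 9505788 to 9530176 on the minus strand, was detected in 67.8% of its cells against 14.6% outside. The B lymphoid list, with as many genes among the 10 largest folds, had 5 of 14 genes in cluster 5 (adjusted p = 0.0044, and 0.16 with genes detected in at least 0.25 of the cells). The T and innate lymphoid list had 3 of 9 genes there (adjusted p = 0.058) and was not over-represented. Cluster 5 held 9 of 41 S phase genes (adjusted p = 0.0019, and 0.97 at a log fold change minimum of 0.25). The T and innate lymphoid-like cluster 12 held 1.57% and 1.56%, a ratio of 0.994 (0.806 to 1.23). It held all 9 listed T and innate lymphoid genes (adjusted p = 4.8e-08), with Trbc2 (1.38), Trbc1 (0.74) and Tcf7 (0.65) in the authors' deposited table. There Trbc2 was detected in 87.2% of its cells, but Trbc1 in only 36.7% and Tcf7 in 37.2%. The mitotic gene Ube2c (1.01) had a larger fold than Trbc1 and Tcf7 in the authors' deposited table. Cluster 12 also held 12 of 17 lymphoid-primed genes (adjusted p = 1.9e-07) and 39 of 50 G2 and M phase genes (4.0e-27).

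The monocyte and dendritic-like clusters were 1, 9 and 11. Cluster 1 held 9.70% of saline and 12.4% of pIC cells, a ratio of 1.28 (1.18 to 1.38). It held 13 of 18 monocyte and dendritic genes (Fisher's exact test, adjusted p = 9.8e-05) and was led in the authors' deposited table by Ms4a6c (1.71), Lyz2 (1.66), Id3 (1.47), Tyrobp (1.34) and Id2 (1.34). Lyz2, the lysozyme gene, was detected in 78.9% of its cells and in 79.6% of all other cells. The granulocyte list was over-represented in cluster 1 too, with 6 of 9 genes (adjusted p = 0.035), a call that ended under both alternative settings (adjusted p = 1 and 0.21). Cluster 9 held 3.18% and 4.17%, a ratio of 1.31 (1.14 to 1.50). It was led in the authors' deposited table by Cd74 (4.05), H2-Ab1 (3.44), H2-Aa (3.35) and H2-Eb1 (3.25), the genes of MHC class II antigen presentation, and held 14 of 18 monocyte and dendritic genes (adjusted p = 0.00030). None of its markers was an S phase or a G2 and M phase list gene (adjusted p = 2.9e-05 and 8.6e-07). Cd74 lies on chromosome 18 from 60803848 to 60812652 on the plus strand. Cluster 11 held 2.13% and 2.24%, a ratio of 1.05 (0.879 to 1.25). It was led by Ly6d (2.73), Cox6a2 (1.74), Irf8 (1.46) and Siglech (1.27) in the authors' deposited table, and held 9 of 18 monocyte and dendritic genes (adjusted p = 0.0078) together with 10 of 17 lymphoid-primed genes (adjusted p = 0.00091, and 0.22 at a log fold change minimum of 0.25). It held 16 of 50 G2 and M phase genes (adjusted p = 0.040), a call that did not hold at that minimum (adjusted p = 1). The monocyte and dendritic list calls of clusters 9 and 11 ended at a log fold change minimum of 0.25 (adjusted p = 0.30 and 0.13).

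The megakaryocyte-like cluster 13 held all 13 listed megakaryocyte genes (Fisher's exact test, adjusted p = 5.8e-11) and 6 of 9 erythroid genes (adjusted p = 0.0021, and 0.073 at a log fold change minimum of 0.25). Among its leading genes in the authors' deposited table were Apoe (2.12), Pf4 (1.06) and Zfpm1 (0.84). Pf4, the platelet factor 4 gene, was detected in 29.6% of its 250 cells and 5.6% of the others. The erythroid transcription factor gene Gata1 was detected in 72.0% against 1.7%.

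Genes that respond to interferon marked clusters 1 and 9. The type I interferon list held 25 genes of the table, of which 20 were markers of cluster 9 (Fisher's exact test, adjusted p = 3.0e-06) and 13 of cluster 1 (adjusted p = 0.0073, and 1 at a log fold change minimum of 0.25). In cluster 9 the largest were Phf11b (1.04), Ly6e (1.03), Samhd1 (0.65) and Ifi27l2a (0.61) in the authors' deposited table. The interferon gamma and antigen presentation list held 15 of 19 genes in cluster 9 (adjusted p = 0.00012), of which 4, Cd74 and the class II genes, also stand in the monocyte and dendritic list. Immediate early stress genes were over-represented in cluster 9 with 10 of 13, including Btg2 (0.68), Junb (0.65) and Klf2 (0.45) in the authors' deposited table (adjusted p = 0.0044, and 0.13 at a log fold change minimum of 0.25). The IL-6, TNF and NF-kB list reached an adjusted p of 0.28 at the lowest. These calls compare a cluster with other cells of both treatments and do not measure a response to pIC.

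**Figure D3:**
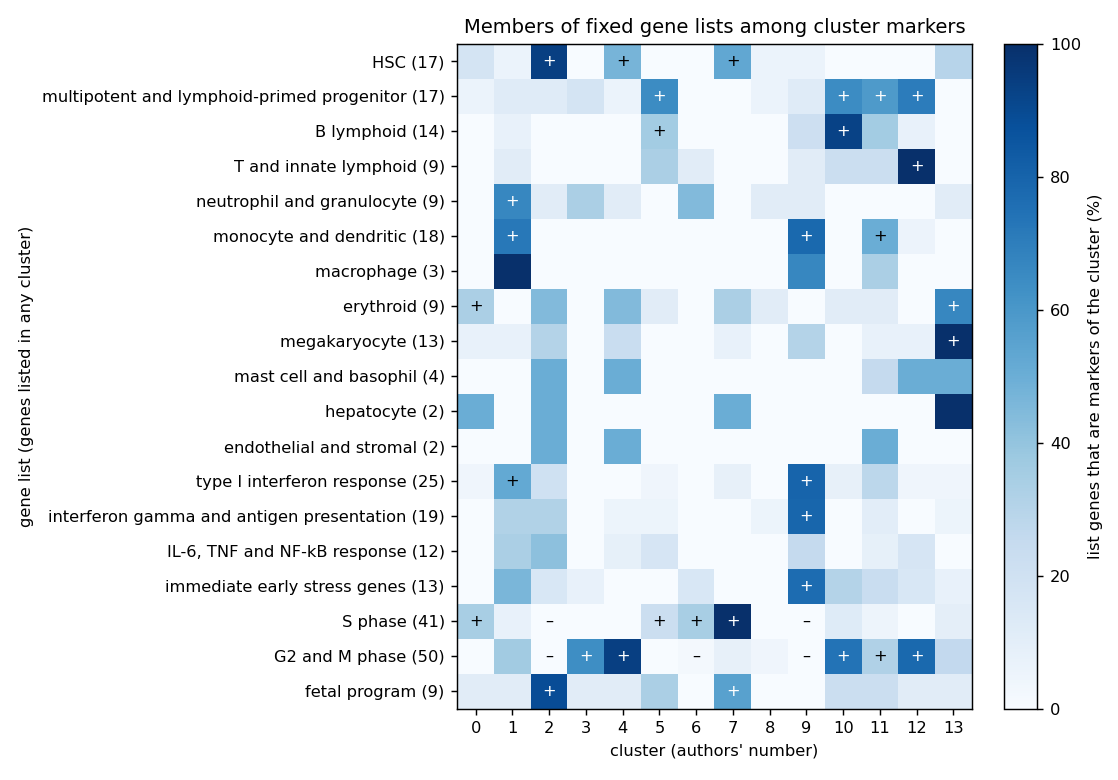
Percent of each fixed list's genes that are markers of each cluster, with lists in rows (in brackets, the number of their genes in the table) and clusters in columns; plus and minus signs mark over- and under-representation at an adjusted Fisher's exact p under 0.05. HSC genes concentrate in clusters 2, 4 and 7, S phase genes in cluster 7 and G2 and M phase genes in clusters 3, 4, 10 and 12.

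Some genes from lists for cells that the sort could have let through were in the table. Of the fixed lists, 2 of 15 hepatocyte, 2 of 16 endothelial and stromal, 3 of 14 macrophage, 4 of 14 mast cell and basophil and 0 of 9 eosinophil genes were in the table. None of these lists was over-represented in a cluster by Fisher's exact test, with lowest adjusted p of 0.094, 0.62, 0.065 and 0.28 for the first 4. With so few genes the test had little power: all 3 macrophage genes were markers of cluster 1 and both hepatocyte genes were markers of cluster 13, the largest overlaps possible there. Some of these genes are not particular to such cells here. Lyz2 of the macrophage list was detected in 79.52% of all cells and Kit of the mast cell list in 75.25%, both chosen after their values were seen. Dlk1 of the hepatocyte list also stands in the fetal program list. The erythroid list had 9 of 20 genes in the table and was over-represented in clusters 0 (3 genes, adjusted p = 0.035) and 13.

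The authors' deposited table of cell numbers gives a Fisher test per cluster over pooled cells, with 10 of the 14 adjusted p-values under 0.05. The other 4, all at an adjusted p of 1 in the authors' deposited table, are clusters 0, 11, 12 and 13. Those p-values take each cell as an independent observation and leave out the spread between the 3 samples of a group. With 3 samples against 3, an exact two-sided permutation test over samples could not go below 0.1.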

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

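Ratios of cluster shares stayed within their counting intervals under each alternative that could be run. Each alternative only changed the reference for the shares, so it multiplied the ratios by a common factor and could not change their order. None of them varied the samples or the clustering, so they do not show how far the ratios depend on these. Leaving the largest cluster out of the totals multiplied the other ratios by 0.993, and the centred log-ratio by 0.973. Leaving out the HSC-like cluster, an alternative chosen after seeing the data, multiplied the other 13 ratios by 0.938 and took 1 of them, that of cluster 11, from 1.05 to 0.983 (0.824 to 1.17). It took cluster 0 from 0.961 (0.898 to 1.03) to 0.901 (0.843 to 0.964), an interval that leaves out 1. The number of markers was 5519, falling to 2275 at a log fold change minimum of 0.25 and to 570 at 0.5, by construction. The pairs of list and cluster over-represented numbered 32, and 21 at a minimum of 0.25. There 19 of the 32 kept the call and 12 lost it, as did 2 of the 5 under-represented pairs, and G2 and M phase in cluster 11 lost it with a change of sign but was not under-represented either (adjusted p = 1); fewer genes pass that minimum. With genes detected in at least 0.25 of the cells, 30 of the 32 kept the call. No paired analysis was possible because the cell numbers are pooled by treatment and carry no replicate letter. For the same reason TMM, DESeq2, limma, the filter on small clusters, the trend setting, log2 totals, the arcsine scale and leaving out each sample were not run. Depth per cell and the spread between fetuses, neither known here, limit every share.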

Other observations

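The test of eGFP over clusters, the sums over phase clusters, the ratios without the HSC-like cluster and the comparisons of detection in this part were chosen after the values they bear on had been seen. The reporter transcript eGFP was a marker of 6 clusters. In the authors' deposited table its largest log fold changes were 0.73 in the B lymphoid-like cluster 10, 0.67 in cluster 11, 0.62 in the T and innate lymphoid-like cluster 12, 0.54 in cluster 9 and 0.52 in the lymphoid-primed cluster 5, with 0.18 in cluster 1. It was detected in 76.9% of cells in cluster 10 and 58.6% in cluster 5 in the authors' deposited table, and in 31.3% of the cells of the 8 clusters that do not list it. Flt3, whose locus drives the switch of the reporter, was a marker of 4 clusters (5, 10, 11 and 12), and eGFP was listed in all 4 of them and in 2 of the other 10. Being listed is a matter of degree: Flt3 was detected in 80.0% to 87.8% of cells of the 4 clusters in the authors' deposited table, and in 65.0% of the cells of the other 10. A candidate explanation is that eGFP follows the history of Flt3 expression (Fisher's exact test over clusters, p = 0.015). Clusters are not replicates, the 31.3% may hold free RNA, and the test does not separate history from current Flt3 expression.

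Pooled shares were also summed by cell cycle phase. The 5 clusters with G2 and M phase genes over-represented (3, 4, 10, 11 and 12) together held 26.7% of saline and 27.0% of pIC cells, a ratio of 1.01. Within them the ratios ran from 0.758 in cluster 4, with HSC genes, to 1.64 in the B lymphoid-like cluster 10. The 4 clusters with S phase genes over-represented held 37.6% and 42.3%, a ratio of 1.13, but this sum rests on clusters 5 (1.37) and 6 (1.58). The 2 clusters that kept the S phase call at a log fold change minimum of 0.25, clusters 0 and 7, together held 23.5% and 21.8%, a ratio of 0.926 (0.877 to 0.977). Whether phase differs between treatments cannot be told apart from the spread between samples, which these tables do not give. Closure from the HSC-like cluster alone, in which its lower share raises all others alike, would leave the other ratios equal. Without that cluster the ratios ran from 0.586 (0.528 to 0.651) in cluster 8 to 1.54 (1.30 to 1.83) in cluster 10, further apart than counting error. Closure of that form alone thus leaves part of the pooled shares unaccounted for. These 2 ratios are the lowest and highest of 13, and their intervals leave out the spread between samples, so this holds for the pooled cells only. Other forms of closure stay open. Shares without absolute cell numbers cannot tell fewer cells in some clusters from more cells in others. That 1 sample of a group carries the difference stays open, since 0 columns hold values of single samples. An effect of pIC is among the open explanations and was not tested.

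The HSC-like cluster, whose share differed most downward, also held 213 of the 237 listed genes with a positive fold but lower detection inside. Among listed genes with a detection share of 0.5 to 0.95 outside, 60.4% were detected less often inside cluster 2, against 0.251% in the other clusters. These genes are part of the same pattern, so the comparison restates it within a narrower range of detection. Fewer molecules per cell in that cluster is a candidate explanation that the comparison cannot test. A gathering of damaged or low-depth cells of mixed types stays open: all 16 HSC markers were detected more often inside than outside, but so were all 14 markers from other cell type lists, and the HSC list gave the cluster its name. Cells outside the cycle with less RNA stay open as well. Cluster 2 had 0 S or G2 and M phase genes among its markers, but so had cluster 9, where 1 of 305 genes in that detection range was detected less often inside.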
